A study of Gallus gallus with 4 samples.

How the data were processed

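Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map binding sites of CTCF, a zinc finger protein that marks insulators and loop anchors, in chicken cells. HD3 is a chicken erythroblast line transformed by avian erythroblastosis virus, and DT40 is a chicken B-lymphoid line. HD3 cells were profiled without induction and after erythroid differentiation had been induced with the protein kinase inhibitor iso-H-7 at raised temperature. Per the labels' protocols, formaldehyde-fixed and sonicated chromatin was precipitated with a custom rabbit antibody against amino acids 86 to 233 of chicken CTCF. The series holds 4 libraries: 1 CTCF library each from non-induced HD3, induced HD3 and DT40, and 1 HD3 input library. The input reads were not analysed here.

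Per the submitters' processing notes, the tools were CASAVA 1.8.2, Bowtie2 and MACS, and the genome build was galGal4. Their parameters, and the control that each MACS run used, are not given in the sources used here. The deposited files are 3 peak lists, 1 per library, so no peak was called on pooled libraries. Each row gives a chromosome, a start, an end, a MACS peak name and a score. The score of a deposited peak is the authors' own value. Apart from the exception below, it was used only to describe, rank or filter peaks within 1 list. Its lowest value was 50 in each list to the nearest whole number, and its scale is not stated in the files. The lists hold no read counts, so the depth of each library is unknown. Scores of different lists were not compared by size. A peak missing from a list was therefore not called there, and this does not show that the site was unoccupied.

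Peaks were counted as overlapping when they shared at least 1 bp. Overlapping peaks of the 3 lists were merged into sites, and each site was classed by the lists that contributed to it. Shares carry exact Clopper-Pearson 95% intervals, and densities carry exact Poisson 95% intervals. These cover counting error only and take peaks or sites as independent. Peaks lay closer together than random placement would put them, as described below, so the intervals are likely too narrow. With 1 library per group there is no test between conditions, and no p-value was computed. Observed overlaps were set beside 100 random placements of the same peak lengths on the same chromosomes. Chromosome spans were taken as the largest peak end in any of the 3 lists, since no galGal4 sequence was used. Macrochromosomes were 1 to 5, intermediate chromosomes 6 to 10, and microchromosomes 11 to 28. The Z chromosome was kept apart.

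For comparisons of rank between libraries, the sites called in both libraries were ranked by score within each list, so that both rankings covered the same sites. Work was done in Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9. The overlap and merging steps were tested on simulated lists, where 6000 of 6000 simulated sites were placed in their class.

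Named sites followed a rule set before the data were examined. It took the 5 highest-scored peaks of each list and the 5 highest-scored sites called in HD3 only or in DT40 only. It also took the 5 highest-scored HD3 sites called in only 1 state, read here as 5 for each state, and the 3 densest 100 kb windows of each list. Other regions named below were chosen after their values were seen. The alternatives fixed in advance were a reciprocal overlap of 50%, midpoints within 500 bp, and a score of at least 100 in all lists or in the list asked about only. Others were equal numbers of top-scored peaks per list, assembled chromosomes only, circular shifts in place of random placement, and another division of the chromosomes. Planned analyses of gene annotation, CpG islands, the CTCF motif and gene lists were not run. They need galGal4 sequence or gene models, and the gene table at hand describes another build. Sites are therefore given by galGal4 coordinates, counted from 1, without gene names.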

Results

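CTCF peaks were mapped in chicken erythroid HD3 cells, with and without induction of differentiation, and in lymphoid DT40 cells, with 1 library for each. The non-induced HD3 list held 8768 peaks, the induced HD3 list 4820 and the DT40 list 13574. Peaks were longest in non-induced HD3, with a median of 1217 bp (interquartile range 1151 to 1289), against 650 bp (590 to 722) after induction and 712 bp (608 to 843) in DT40. The peaks covered 11.3 Mb in non-induced HD3, 3.35 Mb in induced HD3 and 10.6 Mb in DT40. Median caller scores within the lists were 109, 85.9 and 109, in the same order. The median gap between neighbouring peaks was 50.1 kb, 92.0 kb and 26.8 kb. The lists hold no read counts, so the depth is unknown. No library had a replicate, so none of the differences below has a replicate check, and all intervals are 95% intervals for counting error only.

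The first question was how far CTCF sites are shared between the erythroid and lymphoid lines. Merging the lists gave 15733 sites, of which 3684 (23.4%, interval 22.8 to 24.1) were called in all 3 libraries. A further 719 sites were called in both HD3 lists and not in DT40, and 6595 (41.9%, interval 41.1 to 42.7) in DT40 alone, 2767 of them on chromosomes 2, 11 and 20. The order of these classes depended on the lengths of the lists: with the 4820 top-scored peaks of each, 2411 sites were called in all 3 and 1625 in DT40 alone. Of the 9138 sites called in either HD3 list, 74.4% (interval 73.5 to 75.3) were also called in DT40. Of the 13398 DT40 sites, 50.8% (interval 49.9 to 51.6) were called in at least 1 HD3 list. Sites called in both HD3 states were also DT40 sites in 83.7% of cases (interval 82.5 to 84.8). The share was 67.2% (interval 65.8 to 68.6) for sites called in non-induced HD3 and not after induction. With equal numbers of top-scored peaks, a comparison added after the data were seen, these shares were 67.5% and 34.1%. The groups also differed in score within the full non-induced list. For sites called in both HD3 states, median scores were 183 with a DT40 call and 144 without. For sites not called after induction they were 83.3 and 70.5. Sharing with DT40 rose with this score, and the shares were not compared at equal score, so the contrast cannot be separated from score.

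**Figure D1:**
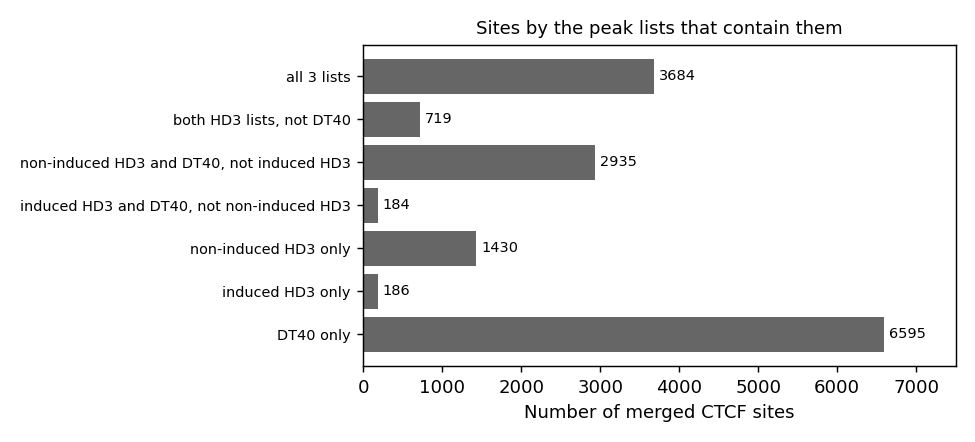
Number of merged CTCF sites (horizontal axis) for each combination of the 3 peak lists (vertical axis). DT40-only sites, 6595, form the largest class, followed by the 3684 sites called in all 3 lists; with equal numbers of peaks the order was the opposite (1625 and 2411).

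All 6 pairwise overlaps were far above random placement, which gave at most 3.68% for any of them. DT40 overlapped 75.5% of non-induced HD3 peaks (interval 74.6 to 76.4), against a mean of 2.98% in 100 random placements. It overlapped 81.0% of induced HD3 peaks (interval 79.8 to 82.1), against a random mean of 2.21%. In the other direction, 50.1% of DT40 peaks (interval 49.2 to 50.9) were overlapped in non-induced HD3 and 28.7% (interval 27.9 to 29.4) in induced HD3. The order of the shares changed with the number of peaks compared. When the 4820 top-scored peaks of each list were compared, the 2 HD3 states shared more peaks with each other than either did with DT40. Non-induced HD3 peaks were then found in induced HD3 in 74.1% of cases and in DT40 in 58.8%, whereas with all peaks the order was the opposite, at 50.2% and 75.5%. For DT40 peaks the gap between the HD3 states nearly closed, with 59.6% found in non-induced HD3 and 56.9% in induced HD3.

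Sharing rose with the caller score. Of the 10% of non-induced HD3 peaks with the lowest scores, 56.1% (interval 52.7 to 59.4) were called in DT40, and of the 10% with the highest scores, 93.7% (interval 91.9 to 95.2). For DT40 peaks called in non-induced HD3, the same shares were 19.8% (interval 17.7 to 22.0) and 89.2% (interval 87.4 to 90.8). Across the 6619 sites called in both non-induced HD3 and DT40, Spearman's rho between the scores was 0.58. Across the 4403 sites called in both HD3 states it was 0.72. These are correlations across sites, which are not independent replicates.

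**Figure D2:**
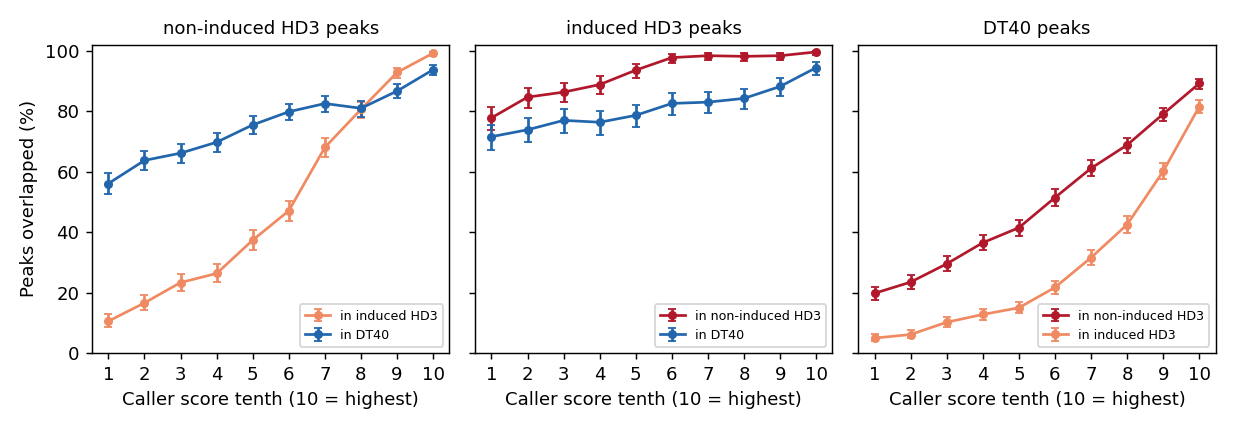
Share of peaks overlapped in each other list (vertical axis, percent, with exact 95% intervals) against score group within the list, from 1 for the lowest 10% of scores to 10 for the highest 10%. Among the highest-scored non-induced HD3 peaks 99.2% were called in induced HD3 and 93.7% in DT40.

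The highest-scored erythroid sites were common to all 3 libraries. Each of the 5 highest-scored peaks of non-induced HD3 and of induced HD3 was overlapped in both other lists. The first was the same in both states, on chromosome 21 at 3032020 to 3033415 in non-induced HD3 (score 2071) and at 3032222 to 3033206 in induced HD3 (score 1407). The second was also common to both, on chromosome 5 at 57480289 to 57481824 in non-induced HD3 (score 2058), with a score of 1107 after induction. The site on chromosome 23 at 5432045 to 5433465 was the fourth in both (scores 1643 and 765). The remaining top peaks of non-induced HD3 lay on chromosome 13 at 9924758 to 9926503 and on chromosome 19 at 6618129 to 6620362. Those of induced HD3 lay on chromosome 1 at 15698734 to 15699602 and on chromosome 27 at 2774550 to 2775519.

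In DT40, 4 peaks shared the highest score of 3100, and 3 of these were called in no HD3 list. They lay on chromosome 14 at 13653199 to 13657940, on chromosome 14 at 14297908 to 14302174 and on chromosome 20 at 2816328 to 2822015. The fourth, on chromosome 14 at 14291893 to 14297809, was overlapped in induced HD3. It ended just before the peak at 14297908 began, so these neighbours may not be separate sites. These 4 peaks were between 4267 and 5917 bp long, several times the DT40 median of 712 bp. The fifth DT40 peak, on chromosome 2 at 137548727 to 137550872 (score 2544), was overlapped in both HD3 lists. The other top sites called in DT40 alone lay on chromosome 1 at 32563527 to 32567512 (score 2368) and on chromosome 19 at 4806045 to 4811416 (score 2343). They were also long, at 3986 and 5372 bp. The site at 13653199 on chromosome 14 lay in a 100 kb window crowded with 27 DT40 peaks.

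The highest-scored sites called in HD3 and not in DT40 were all called in both HD3 states, and the higher of their HD3 scores is given. They lay on chromosome 13 at 8824366 to 8825693 (score 836), chromosome 1 at 15304925 to 15306290 (score 811) and chromosome 12 at 6155660 to 6157092 (score 788). The next were on chromosome 8 at 26796494 to 26797729 (score 706) and chromosome 3 at 81329574 to 81330891 (score 669).

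The second question was how the CTCF sites of HD3 cells differ after induction of erythroid differentiation. The induced list held 54.97% as many peaks as the non-induced list. Of the induced peaks, 92.3% (interval 91.5 to 93.1) were overlapped in non-induced HD3, against a random mean of 2.06%. Conversely, 50.2% of non-induced peaks (interval 49.2 to 51.3) were overlapped after induction. These shares became 75.1% and 74.1% with equal numbers of top-scored peaks, and 59.5% and 32.7% with a reciprocal overlap of 50%. With all peaks, the share overlapped after induction was 10.6% (interval 8.64 to 12.8) for the lowest-scored 10% of non-induced peaks and 99.2% (interval 98.4 to 99.7) for the highest-scored 10%, where 7 of 877 peaks were not overlapped. Requiring midpoints within 500 bp gave 95.8% for that highest group, and a reciprocal overlap of 50% gave 74.2%; both settings were added after the data were seen. Over the 27 numbered chromosomes other than 16, the induced list held between 48.0% (chromosome 28) and 78.1% (chromosome 27) as many peaks as the non-induced list.

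The highest-scored sites called in 1 HD3 state and not in the other were all called in DT40 as well. Those of non-induced cells lay on chromosome 28 at 815914 to 818960 (score 363), chromosome 15 at 5405228 to 5406538 (score 349) and chromosome 20 at 5755706 to 5756883 (score 336). The fourth and the fifth were on chromosome 12 at 6118211 to 6119478 (score 335) and chromosome 26 at 2489415 to 2490833 (score 308). After induction, 370 sites were called that were missing from the non-induced list, and 184 of them (49.7%, interval 44.5 to 54.9; 26.7% with equal numbers of peaks) were also DT40 sites. The number depended strongly on the peaks compared. With equal numbers of top-scored peaks there were 320 such sites shared with DT40 and 879 in induced HD3 alone, and with a score of at least 100 there were 44 and 34. The 5 with the highest scores lay in 3 places. There were 2 neighbours on chromosome 1, at 100391481 to 100392225 (score 231) and 100389488 to 100391349 (score 184). Another 2 lay near the start of chromosome 17, at 79267 to 84741 (score 197) and 69327 to 71307 (score 177). The last lay on chromosome 5 at 56596287 to 56599023 (score 178). Around the 2 neighbours, chromosome 1 at 100300001 to 100400000 held 20 DT40 peaks, 3 in induced HD3 and 0 in non-induced HD3. Coordinates of these sites called in 1 HD3 state are those of the merged sites, so they take in the DT40 peaks as well.

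CTCF peaks were denser on the small chromosomes in every library. In non-induced HD3 there were 7.15 peaks per Mb of macrochromosome (interval 6.94 to 7.37), 10.4 on intermediate chromosomes (interval 9.89 to 10.9) and 14.8 on microchromosomes (interval 14.3 to 15.4). The ratio of micro- to macrochromosome density was 2.08 (interval 1.98 to 2.18) in non-induced HD3, 2.42 (2.27 to 2.59) in induced HD3 and 1.957 (1.88 to 2.03) in DT40. The DT40 ratio was 2.24 without chromosomes 2, 11 and 20, a comparison added after the data were seen. The order of the libraries depended on the lengths of the lists. With equal numbers of top-scored peaks the ratio was 2.58 in non-induced HD3, 2.42 in induced HD3 and 2.64 in DT40. The Z chromosome had 4.93, 2.93 and 6.93 peaks per Mb in non-induced HD3, induced HD3 and DT40. The W chromosome held 6 peaks in non-induced HD3, 5 in induced HD3 and 0 in DT40.

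**Figure D3:**
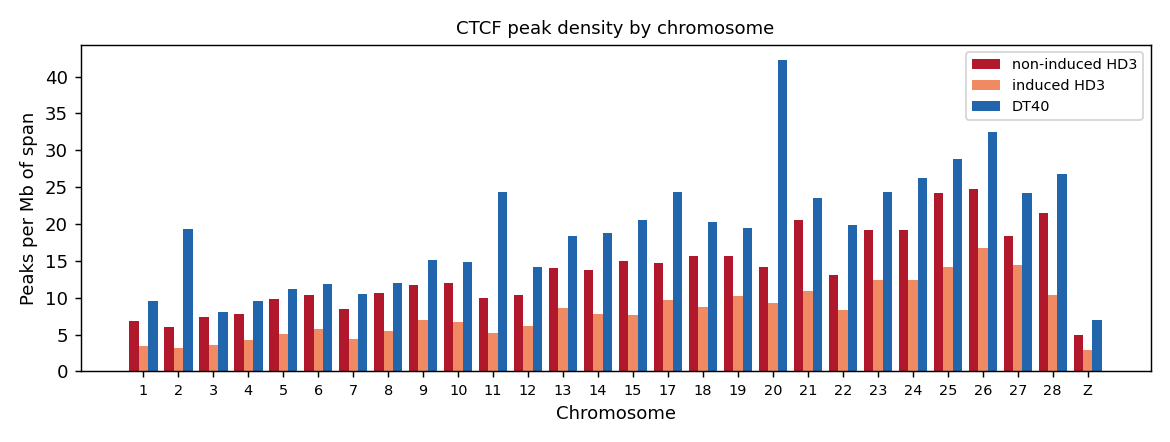
Peaks per Mb of chromosome span (vertical axis) for each library on the numbered chromosomes other than 16 and on Z (horizontal axis), 1 bar per library. The small chromosomes as a class are denser in all libraries, and the DT40 bars of chromosomes 2, 11 and 20 (19.4, 24.3 and 42.2 peaks per Mb) stand above those of similar chromosomes.

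DT40 peaks were unevenly spread over the chromosomes, 3 of which were singled out after their counts were seen. Chromosome 2 held 2883 DT40 peaks against 895 in non-induced HD3, chromosome 11 held 472 against 194, and chromosome 20 held 604 against 203, ratios of 3.22, 2.43 and 2.98. On the other 25 numbered chromosomes or Z, leaving out 16, the ratio lay between 1.10 and 1.66. The small chromosome 16 and the linkage group LGE64 had higher ratios, from few HD3 peaks: 47 DT40 peaks against 8, and 64 against 1. The W chromosome had none in DT40. These 3 chromosomes made up 18.2% of the span and held 2767 (42.0%) of the sites called in DT40 alone. That is 15.2 such sites per Mb (interval 14.6 to 15.7), against 4.67 (interval 4.52 to 4.82) on all other sequences. Their median score in DT40 was 79.4, against 81.7 for DT40-only sites elsewhere. Without these chromosomes, DT40 had 9615 peaks, of which 58.7% (interval 57.7 to 59.7) were overlapped in non-induced HD3, and 3828 sites remained that were called in DT40 alone.

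Several 100 kb windows were crowded in 1 cell line. The densest windows of both HD3 lists lay on chromosome Z between 27000001 and 27300000. There, non-induced HD3 had 41 peaks (15, 13 and 13 per window), induced HD3 had 28 and DT40 had 3. Covered lengths were 50.3 kb, 18.8 kb and 8.89 kb in the same order. In proportion, the difference in covered length from DT40 was smaller than that in peak number, whereas between the HD3 states it was larger. The densest DT40 window, on chromosome 1 at 139300001 to 139400000, held 51 DT40 peaks and 1 in each HD3 list. Next came chromosome 14 at 13600001 to 13700000, with 27 DT40 peaks against 3 and 3. Chromosome 2 at 138100001 to 138200000 also had 27, against 1 and 1. The third densest window of induced HD3, on chromosome 24 at 300001 to 400000, was crowded in every library, with 7, 7 and 8 peaks.

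**Figure D4:**
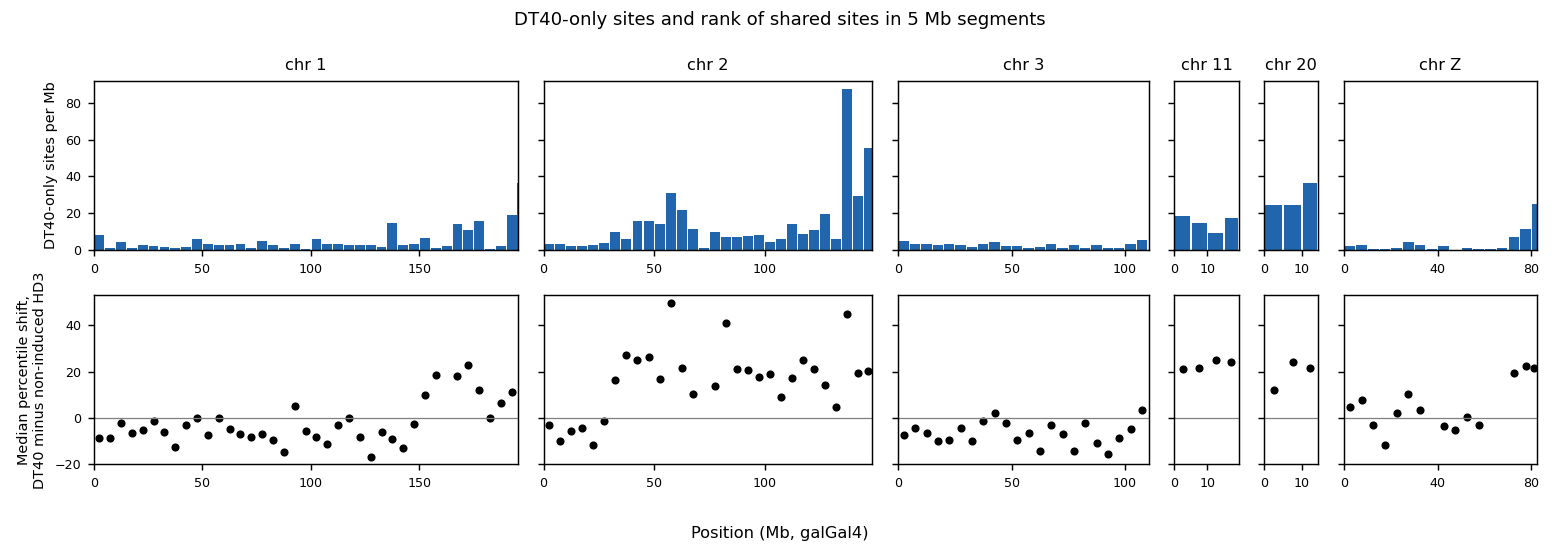
Upper row, sites called in DT40 alone per Mb in 5 Mb segments of 6 chromosomes. Lower row, median difference in score percentile (DT40 minus non-induced HD3) over the sites called in both, for segments with at least 5 such sites. Both are raised over chromosomes 11 and 20, over most of chromosome 2 and near the end of Z, where 139 shared sites beyond 70 Mb had a median difference of 21.4.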

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

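Settings that left out chromosomes 2, 11 and 20 or peaks longer than 3000 bp, and all settings for the last 2 shares given, were chosen after the data were seen. No paired analysis was possible because each group has 1 library, and for the same reason no replicate could be left out. The planned analyses of gene annotation, CpG islands, the motif and gene lists were not run. A score of at least 100 left 4820 non-induced HD3, 1928 induced HD3 and 7443 DT40 peaks. For the overlap shares, the order below is non-induced HD3 in induced HD3 and in DT40, induced HD3 in non-induced HD3 and in DT40, and DT40 in non-induced and in induced HD3. A reciprocal overlap of 50% gave 32.7%, 63.0%, 59.5%, 78.1%, 40.7% and 27.7% (of the 4450 overlapping pairs of HD3 peaks 64.4% passed, and the other 35.6% were too unequal in length to pass). A score of at least 100 gave 38.2%, 71.8%, 96.0%, 83.4%, 47.4% and 21.5%, and applied to the list asked about only, 74.1%, 84.0%, 98.6%, 87.4%, 67.6% and 44.7%. Equal numbers of top-scored peaks gave 74.1%, 58.8%, 75.1%, 57.2%, 59.6% and 56.9%, and 74.4%, 61.8%, 75.4%, 60.3%, 62.7% and 60.04% when chromosomes 2, 11 and 20 were also left out. The 4820 non-induced HD3 peaks with a score of at least 100 equal the full induced list in number. The 2 values of 74.1% are therefore 1 calculation, as are the 2 non-induced ratios of 2.58 below. Midpoints within 500 bp moved 3 of these overlap shares beyond their intervals: non-induced HD3 in DT40 (74.5%), induced in non-induced HD3 (89.96%) and DT40 in non-induced HD3 (48.5%). Without chromosomes 2, 11 and 20 alone, non-induced HD3 in DT40 was 73.6%, and DT40 was found in non-induced HD3 for 58.7% and in induced HD3 for 34.2%. For site classes, in the order of all 3 lists, both HD3 lists, non-induced HD3 with DT40, induced HD3 with DT40, non-induced only, induced only and DT40 only, equal numbers gave 2411, 1163, 425, 320, 821, 879 and 1625 sites. A score of at least 100 gave 1559, 281, 1904, 44, 1076, 34 and 3868. Reciprocal overlap gave 443 sites for both HD3 lists, 561 for induced HD3 with DT40, 2665 for non-induced only and 596 for induced only. DT40-only sites numbered 3828 without chromosomes 2, 11 and 20. The micro- to macrochromosome ratio stayed above 1 in every setting: with a score of at least 100 it was 2.58, 2.90 and 2.40 (non-induced HD3, induced HD3, DT40), and with equal numbers 2.58 and 2.64 for non-induced HD3 and DT40. Counting 1 to 8 and Z as macrochromosomes gave 1.95 and 2.23 in the HD3 lists, and leaving out chromosomes 2, 11 and 20 gave 2.24 in DT40. The share of DT40-only sites on those chromosomes was 38.6% with reciprocal overlap, 37.5% with a score of at least 100 and 45.8% with equal numbers. The share of the highest-scored 10% of non-induced peaks called after induction was 74.2% with reciprocal overlap and 95.8% with midpoints within 500 bp. Restriction to assembled chromosomes, leaving out long peaks and circular shifts moved no share they were run on beyond its interval, no random mean beyond its spread and no count by over 1.5 times, though a single circular shift gave 6.97% for induced HD3 in DT40. Lower counts under a stricter score follow from its construction, and apart from the lengths of HD3 pairs the cause of the other shifts was not tested.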

Other observations

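The tests of explanations in this part, the comparison across segments and the segment bounds were chosen after the results they bear on were seen; the overlap of all peaks was planned. The peaks of each list lay closer together than random placement on the same chromosomes would put them. A neighbour within 10 kb was found for 27.6% of non-induced HD3 peaks (highest of 100 random placements 21.2%), 18.5% of induced HD3 peaks (highest 13.0%) and 45.3% of DT40 peaks (highest 30.3%). Without chromosomes 2, 11 and 20 the DT40 share was 40.0%. Random placement takes no account of regional gene density, which was not examined, so it is argued against only as a description of these lists, and what places the peaks together stays open. Peaks longer than 3000 bp numbered 44 in non-induced HD3, 22 in induced HD3 and 63 in DT40, of which 4, 10 and 48 were overlapped in neither other list.

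DT40-only sites were also unevenly spread within chromosomes. On chromosome 2 there were 2.84 DT40-only sites per Mb in the first 25 Mb (interval 2.22 to 3.58) and 16.2 per Mb beyond (interval 15.5 to 16.9). Non-induced HD3 peaks went from 7.80 to 5.65 per Mb. Beyond 25 Mb, single 5 Mb segments held between 1.20 and 87.4 DT40-only sites per Mb. The segments from 135000001 to the end held 437, 147 and 211 of the 2006 DT40-only sites beyond 25 Mb. Chromosome 1 had 3.37 per Mb up to 150 Mb and 8.33 beyond, but its segments varied from 0.8 to 14.8 before that point and from 0.8 to 19.2 after it, leaving out a short end fragment with 10 sites. Its shared sites had a median rank difference (DT40 minus non-induced HD3) of -6.60 percentile points before that point, where 36.2% ranked higher in DT40, and of 12.4 after it, where 76.0% did. Chromosome Z had 1.54 up to 70 Mb and 12.2 beyond, where non-induced HD3 peaks also rose, from 3.70 to 11.9 per Mb. A deeper or more sensitive DT40 library is argued against as the whole cause, since greater depth gives no reason for shared sites to rank higher on some chromosomes, and the share of sites ranking higher in DT40 was 35.8 percentage points above the rest on chromosomes 2, 11 and 20 (interval 28.1 to 41.6, from 1000 resamples of 5 Mb segments). These chromosomes were singled out by their numbers of peaks, not by these ranks. Counts and ranks both come from the same DT40 list, however, and they went together across segments. The ranks are therefore not independent of that choice, and the interval does not allow for it. A candidate explanation is a difference in DNA copy number between the cell lines, which would raise signal at nearly all sites of a region; of the 1120 shared sites on these chromosomes, 77.9% ranked higher in DT40 than in non-induced HD3, against 42.2% elsewhere (ranks over the same sites force a rise in 1 part to be offset in another). A regional gain of CTCF occupancy in lymphoid cells would raise ranks in the same way, so these ranks cannot tell it from copy number. Both stay open and untested, because read coverage and a DT40 input were not used here. The control of each MACS run is also not given.

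The shorter list after induction was examined in the same way. Loss of sites regardless of their score is argued against, since 0.798% of the highest-scored 10% of non-induced peaks were missing after induction (interval 0.322 to 1.64), while 50.2% of all non-induced peaks were still called. A less sensitive induced library may account for the pattern, as it requires the strongest peaks to be kept, and 99.2% of them were. The share was 95.8% with midpoints within 500 bp and 74.2% with a reciprocal overlap of 50%, so both readings rest on counting any overlap or nearby midpoints; among the pairs of this highest group, 27.6% were too unequal in length for the reciprocal rule. A general weakening of CTCF binding on differentiation makes the same prediction and stays open, because the lists hold no read counts.

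Segments with more DT40-only sites also had larger rank differences at shared sites. Spearman's rho across 204 segments of 5 Mb was 0.57, and it was 0.39 across the 168 segments outside chromosomes 2, 11 and 20. Leaving out chromosomes 1 and Z as well gave 0.497 across 116 segments, so the relation was not limited to these 5 chromosomes. Neighbouring segments are not independent, so no p-value is given. The density of DT40-only sites was not adjusted for chromosome size or overall peak density, which also differ between segments.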
